A study of Drosophila melanogaster with 10 samples.

How the data were processed

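Gene expression was measured on 2-colour spotted arrays of Drosophila melanogaster. Each array carried labelled RNA from male and from female genital imaginal discs, the larval primordia of the genitalia and terminal structures. They were dissected late in the third larval instar after gut clearing. Per the labels' protocols, total RNA of pooled discs was amplified as aminoallyl cRNA from poly(A)+ transcripts and coupled to Cy5 or Cy3. There were 5 arrays of the Berlin strain and 5 of the Canton S strain, and the series' design text calls the replicates independent biological samples. The male sample carried Cy5 on 2 Berlin and 3 Canton S arrays and Cy3 on the others.

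The deposited table holds 1 log2 ratio of the channels per probe and array, with replicates not pooled. The submitters' processing notes name limma, with no version or role. The scanner, background correction, within-array normalization, centring and spot filter are not given in the sources used here, nor is the numerator of the ratio. The log base is not given either and was taken as 2, which is limma's convention. The values do not settle it, since the extremes of -16.4 and 17.3 lie beyond even a log2 ratio of positive whole 16-bit intensities. All fold values rest on base 2. Between 18.1% and 55.4% of the 15744 probes had a value on an array, and the other cells were empty. There are no channel intensities in the table, so brightness, saturation and intensity-dependent bias could not be examined. The number of arrays limits the precision. Array means of the deposited log2 values ranged from -0.063 to 0.14. Array medians were -0.28, -0.051, -0.047, -0.022 and 0.0012 for Berlin replicates 1 to 5 and 0.26, 0.0032, 0.030, -0.035 and 0.56 for Canton S replicates 1 to 5. Log base, centring and direction stay unknown.

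Probes are identified by plate and well on 41 printing plates of 384 wells. None of the probe identifiers appeared in the reference table of 17872 genes used here (0 matches), and the file does not pair them with genes. The 27 gene lists fixed before the data were examined, the comparison of X-linked with autosomal genes, the check of the sign with the male-specific roX RNAs and the averaging of probes per gene were therefore not run, and each probe is one row. The naming rule fixed beforehand took the highest and lowest ratios among calls with the same sign on every measured array. Because probes have no gene names here, only its first 2 probes on each side are named, and none for the strain difference.

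The direction was set by a rule fixed beforehand. Over all probes, pairs of arrays with opposite dye orientation had a mean correlation across probes of 0.25 (25 pairs, from -0.61 to 0.70), against 0.51 (20 pairs, from -0.11 to 0.86) for the same orientation. By that rule the deposited values count as already turned the same way for the dye swap. Over the 4129 tested probes that the fit described below did not call, the means were -0.19 for opposite and 0.28 for the same orientation. Those are the signs that the rule reads as dye ratios, so its outcome rests on the other probes. The uncalled probes were selected by the fit, and the report keeps the reading that the rule gives. Each sample description words the comparison as female to male, so female over male is the likely reading. It could not be checked against a known sex-specific transcript, so the report uses the deposited sign, in place of the planned turn to male over female, and speaks of the positive and the negative side. If the ratio runs the other way, both sides exchange and no count or size changes.

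Control spots (32 rows) were left out of the fits. A probe was tested where each strain had at least 3 measured arrays and both dye orientations were measured, which left 4514 probes. Models were fitted with limma 3.58.1 (lmFit, eBayes) in R 4.3.3 on the deposited values of all 10 arrays, with a mean per strain and a probe-specific dye term. Each contrast was fitted as a coefficient of its own, since contrasts formed after the fit are approximate where values are missing. The contrasts were the mean of both strains, each strain alone and Berlin minus Canton S. P-values were adjusted over the 4514 probes with the Benjamini-Hochberg method, and a call is an adjusted p below 0.05. Figures were drawn with matplotlib 3.10.9.

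The fits were tested on simulated data with the missing cells and the spread of the real arrays, a simulated dye effect and independent noise between probes, run on 4514 probes. A probe's simulated dye effect had one size on every array, and patterns shared by only some arrays were not simulated. In the mean of both strains, simulated changes of 1, 2, 3 and 4 on the log2 scale were called in 8%, 68%, 90% and 96% of probes (50 of each size), and 1.50% of calls were false. In Berlin alone the shares for these sizes were 0%, 32%, 70% and 88%, and in Canton S alone 2%, 38%, 72% and 88%. A simulated strain difference of 1, 2, 3 or 4 was called in 0%, 0%, 18% and 22% of probes.

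Alternatives fixed beforehand were no dye term, separate fits per strain, median centring, scaling of the arrays (planned on the median absolute deviation and run on the median absolute value), only completely measured probes, robust eBayes with statmod 1.5.0, array weights, a threshold of 0.01, a test against a 1.2-fold change, a replicate block and leaving out each array. A further 3 were chosen after seeing the data, and the closing section names them. The limit of 1 for the median absolute deviation that separates widely spread arrays was also set after seeing the data.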

Results

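Male and female genital discs of 2 wild-type strains of Drosophila melanogaster, Berlin and Canton S, were compared directly on 10 arrays, 5 per strain. The discs were taken from larvae that had just cleared the gut, a stage that follows a high ecdysone pulse. The design asks which transcripts differ between the sexes in the tissue that forms the genitalia, and whether they do so in both genetic backgrounds. Of 15744 probes, 10022 had a value on at least 1 array, 2284 had one on all 10 arrays, and 5722 had none. Berlin arrays had values for 4918 ± 857 probes (SD, n = 5) and Canton S arrays for 6015 ± 2134 (SD, n = 5). The fewest, 2848, were on Canton S replicate 4 and the most, 8724, on Canton S replicate 3.

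The arrays differed in spread. The median absolute deviation of the log2 ratios lay between 0.37 and 0.88 on 5 arrays (Berlin replicates 2 to 5 and Canton S replicate 3) and between 1.22 and 2.17 on the other 5 (Berlin replicate 1 and Canton S replicates 1, 2, 4 and 5). Canton S thus had 4 widely spread arrays and Berlin 1. This difference in number did not pass a two-sided Fisher's exact test (p = 0.206).

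Averaged over both strains, 385 of 4514 tested probes (8.53%) differed between the sexes in limma's moderated test with Benjamini-Hochberg adjustment. Of these, 370 lay on the positive side and 15 on the negative side. The positive probes had a median ratio of 2.47 on the log2 scale, a 5.56-fold difference, with quartiles of 3.61-fold and 8.14-fold. At least a 2-fold difference was estimated for 369 of them, at least 4-fold for 261, at least 8-fold for 97 and at least 16-fold for 9. The 15 negative probes were fewer and closer to equality, with a median of 2.38-fold, 3 at 4-fold or more and none at 8-fold. The typical standard error of a called probe was 0.35 on the log2 scale. Which sex the positive side stands for is likely female by the wording of the sample descriptions and is not settled by the values. If the values were instead Cy5 over Cy3 ratios, the sex effect would be the dye term, for which limma called 0 probes. The dye term had 1238 probes at an unadjusted p below 0.05, more than the 540 of the mean of both strains. Of the 2284 probes measured on all 10 arrays, 91 were among the 385 calls, and 86 were called when only those probes were fitted and adjusted. The negative count of 15 was 43 with array weights, 27 with the arrays scaled and 6 in the test against a 1.2-fold change. The count was 4 at a threshold of 0.01, with only fully measured probes or with the replicate block. It was 7 without Berlin replicate 3, 8 without Canton S replicate 1 or 3, 9 without Berlin replicate 2, 4 or 5 and 23 without Canton S replicate 4.

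The probe with the highest ratio was DAC034O07 on printing plate 34, at 5.42 ± 0.56 (SE) on the log2 scale, a 42.8-fold difference (limma adjusted p = 0.000397). Its ratios averaged 6.03 ± 1.23 (SD, n = 3) on Berlin arrays and 4.81 ± 2.15 (SD, n = 3) on Canton S arrays. Its estimate was 6.31 without Berlin replicate 3 or without Canton S replicate 5, and 8.95 with the arrays scaled. DAC028I08 on plate 28 followed at 5.27 ± 0.68 (SE), or 38.5-fold (limma adjusted p = 0.000669), with 5.34 ± 1.21 (SD, n = 3) in Berlin and 4.19 ± 2.92 (SD, n = 4) in Canton S. Its estimate was 3.62 without Canton S replicate 2, 4.54 with array weights, 6.77 with the arrays scaled and 7.12 without Berlin replicate 3. It stood above DAC034O07 without Berlin replicate 3, and also without Berlin replicate 4, at 5.21 against 5.06. On the negative side the lowest was DAC020C16 on plate 20 at -2.88 ± 0.68 (SE), or 7.37-fold (limma adjusted p = 0.0204). Its Berlin ratios averaged -1.91 ± 0.39 (SD, n = 4), and its Canton S ratios -4.43 ± 3.67 (SD, n = 4) with a range from -8.02 to -1.01. On Canton S replicates 1 and 5, which had a correlation of 0.80 over uncalled probes, it stood at -8.02 and -7.17. On Canton S replicates 2 and 4 it stood at -1.01 and -1.53. Its call was lost without Berlin replicate 2, Berlin replicate 3 or Canton S replicate 5, with limma adjusted p of 0.0887, 0.0884 and 0.0505, and it did not pass in Berlin alone (limma adjusted p = 0.588). Its estimate was -3.58 without Canton S replicate 2. DAC037A11 on plate 37 stood at -2.62 ± 0.34 (SE), or 6.16-fold (limma adjusted p = 0.000517), with -2.25 ± 0.16 (SD, n = 5) in Berlin and -3.23 ± 1.71 (SD, n = 3) in Canton S. It stood below DAC020C16 with the arrays scaled, at -3.48 against -2.81. The same held without Canton S replicate 1, at -2.62 against -2.43, and without Canton S replicate 5, at -3.11 against -2.56. All 4 had one sign on every array that measured them, by the rule that chose them. Read as Cy5 over Cy3 ratios, none of the 4 passes in limma's test. A sign kept over both dye orientations favours that outcome, so it does not bear on which reading holds.

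**Figure D1:**
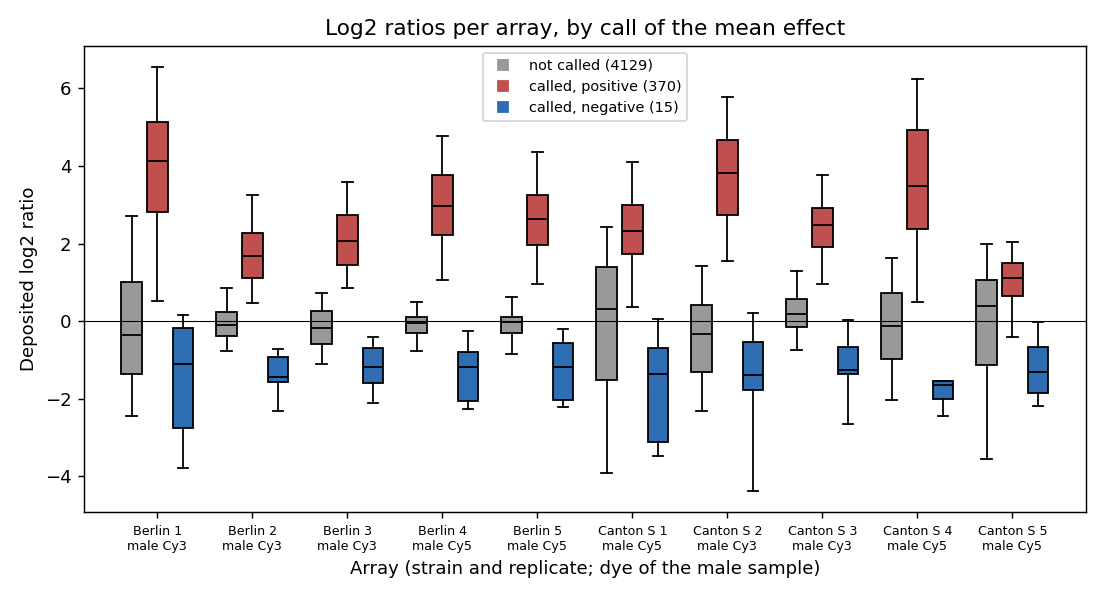
Deposited log2 ratios (vertical axis) on each of the 10 arrays (horizontal axis, with the dye of the male sample), for the 4129 probes not called, the 370 called positive and the 15 called negative in the mean of both strains. Boxes are quartiles with the median, and whiskers reach the percentiles 5 and 95. The median of the positive probes is above 0 on every array, from 1.10 on Canton S replicate 5 to 4.13 on Berlin replicate 1, while the spread of the uncalled probes differs widely between arrays.

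Most positive calls had one sign on every array. Of the 370, 312 were above 0 on every array that measured them, and 8 of the 15 negative probes were below 0 on every such array. Among 4129 uncalled probes, 0.702% had a single sign throughout, against 0.597% expected from coin tosses. These shares describe calls selected for a steady ratio between arrays. The median of the positive probes' mean log2 ratios was 2.31 over the arrays with the male sample in Cy5 and 2.68 over those with it in Cy3.

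Within Berlin, 286 probes were called, 280 on the positive side and 6 on the negative side. The positive ones had a median of 6.72-fold, and 236 were at 4-fold or more. Of the 286, 282 were also called in the mean of both strains, and 282 had an estimate of the same sign in Canton S. Without Berlin replicate 4 the count was 93, with 0 on the negative side, and without Berlin replicate 5 it was 130. With array weights, 452 positive and 213 negative probes were called (68.0% positive, against 97.9%), and with the arrays scaled to one median absolute value 352 positive and 91 negative (79.5% positive), so calls rose on both sides. The 6 negative calls became 18 with Berlin fitted by itself and 64 without the 5 widely spread arrays, an alternative chosen after seeing the data.

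Within Canton S, 274 probes were called, 266 on the positive side and 8 on the negative side, with a median of 6.51-fold among the positive ones and 234 at 4-fold or more. Of the 274, 271 had an estimate of the same sign in Berlin. This count was less stable than that of the mean. Without Canton S replicate 2, limma called none, with 868 probes at an unadjusted p below 0.05, and after scaling the arrays to one median absolute value it also called none, with 216 such probes. Without Canton S replicate 1 or 3 the counts were 148 and 115, and with each array centred on its median 171. When the sexes were swapped within Canton S arrays, 3 of 16 assignments, the real one included, gave at least 274 calls. The highest other assignment gave 533. The 8 negative calls became 31 without Canton S replicate 4 and 17 with array weights, 5 without Berlin replicate 2, 4 or 5 or Canton S replicate 1, and 4 without Canton S replicate 3.

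Both strains called 218 probes on the positive side, where independent lists of these lengths would share 16.5, and 3 on the negative side, where they would share 0.0106. No probe was called in opposite directions. The strains' RNA samples were separate, but for each probe the joint fit shares 1 dye estimate and 1 estimate of spread. Each strain was also fitted by itself, with its own dye term and estimate of spread. Over 4154 probes of the same set, 202 positive and 3 negative probes were then shared, against 17.1 and 0.00939 expected. A dye effect in values not turned before deposit would also be shared by both strains, so this overlap does not tell it from sex. Across the tested probes of the joint fit, the strains' estimates had a Pearson correlation of 0.63 and a Spearman correlation of 0.0076. Over the 385 called probes Pearson's correlation was 0.80, and over the uncalled probes it was -0.21. Probes are not independent replicates, and both groups were selected on the mean of the strains, which by itself moves these correlations. The number of shared calls was 0 without Canton S replicate 2 or with the arrays scaled. It was 85, all positive, without Berlin replicate 4, 117 without Berlin replicate 5, 132 without Canton S replicate 1 and 95 without Canton S replicate 3. With array weights, 6 negative probes were shared.

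**Figure D2:**
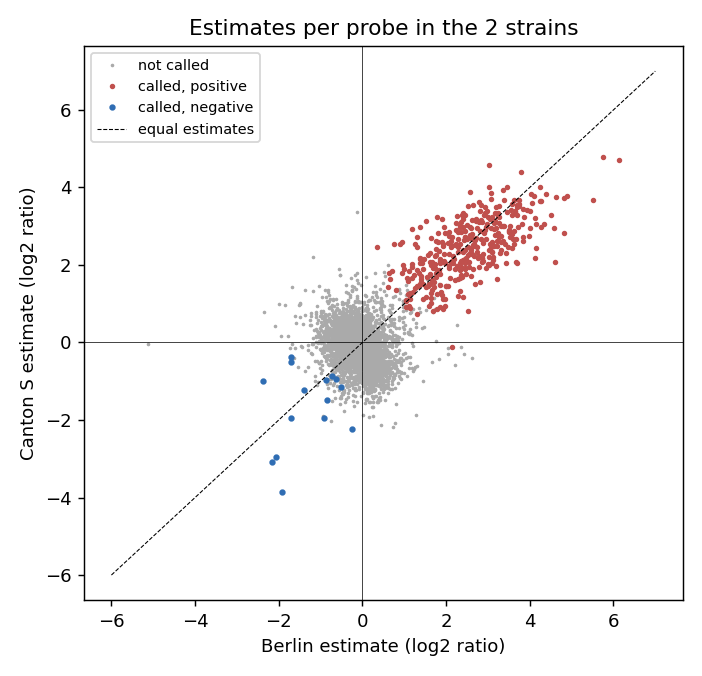
Estimated log2 ratio per probe in Berlin (horizontal axis) and in Canton S (vertical axis) from the joint fit, for all 4514 tested probes, coloured by the call in the mean of both strains. The dashed line marks equal estimates. The called positive probes lie apart along the line, while the uncalled probes form a cloud around 0.

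The difference between the strains in this ratio was tested directly. None of the 4514 probes passed in limma's test, with a smallest adjusted p of 0.871, and 153 had an unadjusted p below 0.05. The 95% interval of a probe's strain difference had a typical half-width of 1.35 on the log2 scale, so a difference of up to 2.55-fold lies within it even where the estimate is 0. Among the 339 probes called in either strain, 21 (6.19%) had an unadjusted p below 0.05. Over the 370 positive probes, the median difference, Berlin minus Canton S, was 0.076 on the log2 scale, and 206 had the larger estimate in Berlin. The per-array median of these probes was 2.70 ± 0.94 in Berlin (SD, n = 5) and 2.64 ± 1.07 in Canton S (SD, n = 5), a difference of 0.061 (two-sided exact permutation test over 252 splits, p = 0.929). In data simulated with independent noise between probes, a strain difference of 2 on the log2 scale was called in 0% of probes and one of 4 in 22%. Most strain differences of these sizes would thus go undetected even there. Patterns shared by only some of the real arrays were not simulated, so these shares are a guide only.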

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

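The tests on the widely spread arrays in this part were chosen after the result was seen. Per-array measures were screened for an outlying array in 14 groups of arrays of one strain, and 3 held one, where chance gives about 1 in 20 groups. Berlin replicate 1 stood apart from the other Berlin arrays in its median log2 ratio, -0.28 against -0.051 to 0.0012, and in its median absolute deviation, 1.90 against 0.37 to 0.65. Berlin replicate 2 had a median of -1.45 over the 15 negative probes, against -1.18 to -1.11 on the other Berlin arrays.

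Berlin replicate 1 was one of 5 arrays with a median absolute deviation of 1.22 to 2.17, against 0.37 to 0.88 on the others. A dye bias in values that were turned for the swap would give arrays of opposite orientation opposite signs. Over uncalled probes, all 6 pairs among Berlin replicate 1 and Canton S replicates 1, 2 and 5 had the sign this predicts, with correlations from -0.79 to 0.80. Of the 4 pairs with Canton S replicate 4, 0 did, with correlations from -0.26 to 0.17. This argues against a dye bias shared by all 5 arrays only if the dye label and the turning of Canton S replicate 4 are right. The 4 pairs share that array and all had the reverse sign, so they cannot check its label or turning. Canton S replicate 4 was set apart after these signs were seen, so a dye bias in the other 4 stays open. Strain stays open too, since 4 of 5 Canton S arrays but 1 of 5 Berlin arrays were wide (two-sided Fisher's exact p = 0.206), and no biological explanation beyond strain was tested.

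Control spots entered no comparison, and some of them held a negative signal. DACControlB07 and DACControlD07, measured on 2 arrays each, were positive, and DACControlB08, DACControlC07 and DACControlC08 had both signs. DACControlC05 had a mean log2 ratio of -2.59 and was negative on all 10 arrays, from -3.61 to -1.23. DACControlB05 averaged -2.60 over 7 arrays and DACControlD05 averaged -2.49 over 8, negative on each. These arrays cover both dye orientations. DACControlA05 averaged -3.35 over 3 arrays, negative on each. What these spots contain is not given in the sources used here. Spots whose ratio reflects the dyes and not sex would keep one sign over both orientations if the values had not been turned for the swap, and in that reading the sex effect is the dye term, with 0 calls in limma (1238 probes at an unadjusted p below 0.05). Whether they are such spots was not tested.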

How the results depend on the processing

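The alternatives were fixed before the data were examined, except leaving out the 5 wide arrays, leaving out plates 1 and 2 and reading the values as Cy5 over Cy3. Scaling was also not run as fixed: it was planned on the median absolute deviation and run on the median absolute value. The mean of both strains had 331 (without Canton S replicate 3) to 401 (without Canton S replicate 4) calls when single arrays were left out, 375 with no dye term, 366 with centring, 374 with scaling, 469 with array weights, and 426 without the 5 wide arrays, 337 of them among the 385. Only the fully measured probes gave 86 calls, in Berlin 67, in Canton S 51 and shared 45, from 2284 tested probes. Read as Cy5 over Cy3, the sex effect is the dye term, with 0 calls in limma. It had 1238 probes at an unadjusted p below 0.05, against 540 for the mean as deposited. The terms of DAC034O07, DAC028I08, DAC037A11 and DAC020C16 are -0.33, -1.20, 0.43 and -1.16 as male over female, and of the same size with the opposite sign as female over male. Which of them change sign depends on the direction of the deposited ratio, which is not settled. Leaving out single arrays gave 93 to 311 calls in Berlin, 0 to 300 in Canton S, 0 to 258 shared and 0 for the strain difference. Centring gave 171 calls in Canton S and 139 shared. Scaling gave 443 in Berlin, 0 in Canton S (216 at an unadjusted p below 0.05) and 0 shared. Array weights gave 665 in Berlin, and leaving out the 5 wide arrays 446, with 1 Canton S array assumed to vary like the others. A threshold of 0.01 gave 167 in Berlin, 121 in Canton S and 82 shared. Except for the fully measured probes, the cause was not tested. DAC020C16 passed 0.05 but not 0.01, and its adjusted p was 0.0887 without Berlin replicate 2, 0.0884 without Berlin replicate 3 and 0.0505 without Canton S replicate 5. The strain difference had 0 calls in limma under each alternative that gave it, leaving out single arrays included, with 45 to 734 probes at an unadjusted p below 0.05. Gene lists and the X-linked comparison were not run for lack of gene names, one row per probe changes nothing here, separate fits give neither a mean of both strains nor a strain difference, and the Cy5 over Cy3 reading was run for the mean only.

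The replicate numbers are shared by the strains, and whether they mark pairs of arrays is not settled. Correlations of the deviations of same-numbered arrays from their strain means were -0.60, -0.48, -0.017, -0.12 and 0.50. These values mix with the dye orientation and spread of the arrays, and differently numbered arrays were not compared. With the replicate number as a block and no dye term, 3737 probes could be tested. Of these, 261 were called in the mean of both strains (257 positive and 4 negative), 126 in Berlin, 0 in Canton S (341 at an unadjusted p below 0.05), 0 shared and 0 for the strain difference.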

Other observations

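In this part, the tests of reassigned arrays and both tests of dye on the one-sided calls were chosen after the results were seen, and one of these replaced an earlier test that could not separate the readings. Probes on printing plates 1 and 2 were measured rarely, in 6.20% and 14.8% of their cells, and 7 and 36 of them were tested with no call. Their median ratios were far from 0 on Canton S replicate 5, at -3.48 and -3.27, on Berlin replicate 1, at 2.23 and 1.49, on Canton S replicate 1, at -2.21 and -1.06, and on Canton S replicate 4, at 2.00 and 0.73, and nearer to 0 on Berlin replicate 4, at 0.055 and -0.24.

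The calls of the mean lie mostly on one side, 370 against 15 (426 against 43 with array weights, 347 against 27 with scaling, and 7 to 23 negative when single arrays are left out), and a dye bias in values turned before deposit would change sign with the dye. In the 5 narrow arrays, of the 307 probes with a mean of at least 1 in one orientation 95.8% were above 0 in the other, and of 299 selected in the other 99.3% were above 0 in the first, which argues against it in these arrays. They are Berlin replicates 2 to 5 and Canton S replicate 3. The check therefore holds no dye swap within Canton S and none of the widely spread arrays. If the values had been deposited as dye ratios, the shared sign could be a dye effect and sex differences would change sign with the dye. Of 3289 probes measured on all narrow arrays, 0 were at least 2-fold on every array with a sign that followed the dye, and 208 with one sign throughout (206 positive), but without a probe of a known sex-specific gene this reading stays open. Among 3308 untested probes with at least 2 values, 483 had a mean of at least 1 and 342 of at most -1, which is 58.5% positive (exact 95% interval 55.1% to 61.9%) against 93.4% among tested probes, so whether thin coverage hid negative probes also stays open, as does sex itself.

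Called probes had more gaps: of the 385 called, 23.6% were measured on all 10 arrays, against 53.1% of uncalled probes (two-sided Fisher's exact p = 1.46e-29, over probes, which are not independent). Put the other way, 3.98% of fully measured probes and 13.2% of those with gaps were called. Removing values from fully measured probes to mimic the gaps left 3.86% of them called (SD 0.169 over 20 repeats). This argues against fewer values by themselves as the cause. The fully measured probes kept their own noise, so whether probes with gaps have noisier values was not tested. A candidate explanation is that spots were left empty where one channel was dim. Larger ratios would then go with fewer arrays, but over the 370 positive probes the rank correlation was 0.16 (permutation p = 0.00203). This argues against it within these calls only. They were selected for a large steady ratio and at least 3 measured arrays per strain, so probes with fewer values are not covered and the explanation stays open. Of the positive calls 22.7% were measured on all 10 arrays, and of the negative calls 46.7%. Channel intensities were not analysed here.

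Swapping the sexes at random within arrays shows what other assignments give. For the mean of both strains, 1 of 100 assignments, the real one, gave as many as 385 calls. The highest other, with Canton S replicate 5 swapped, gave 261. A swap turned the sign of an array's values together with its dye, so the number of calls depends on the sign that the arrays share. A dye effect in values not turned before deposit would also favour the real assignment, so these draws do not tell it from sex. Within Berlin the 16 assignments are too few for a share under 0.05, with 286 real calls against 23 for the highest other. Within Canton S they are also too few for such a share, but 3 of 16, the real one included, gave at least the real 274 calls. The number of Canton S calls thus does not set the real assignment apart from the others. The highest other gave 533, with replicates 2 and 4 swapped. Over uncalled probes, replicate 2 had correlations of -0.76 and -0.70 with replicates 1 and 5, and replicate 4 of -0.26 and -0.24. This swap thus aligns a pattern of the widely spread Canton S arrays, and whether that pattern reflects sex, dye or another source is not settled. For the strain difference, where limma called 0 probes (153 at an unadjusted p below 0.05), all 99 splits that could be fitted gave at least that count, as any split must, so their number decides nothing. A split that put Berlin replicates 1, 4 and 5 with Canton S replicates 2 and 4 gave 2121 calls, which points to a structure of the arrays that crosses the strains.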
